A study of Mus musculus with 6 samples.

How the data were processed

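RNA was measured by sequencing in glomeruli, the filtering units of the kidney, isolated from FVB/N mice. Per the labels' protocols, mice were perfused with iron oxide particles, the kidneys were digested with collagenase and deoxyribonuclease, and glomeruli loaded with iron were pulled out with a magnet before total RNA was extracted with a column kit and Illumina libraries were made. Such a preparation holds podocytes, parietal epithelial, mesangial and endothelial cells, and any leukocytes and tubule fragments that come with them. The labels give 3 control libraries, from mice with floxed Klf4 alleles, and 3 knockout libraries, from mice that also carry a Cre recombinase that is active in podocytes. No group carried Cre without the floxed alleles, so effects of Cre and of Klf4 loss are not separable in this design. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these libraries, part of which may be technical. All 6 libraries carry the same lane label, and the labels name no batch.

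The deposited table holds RPKM (reads scaled by gene length in kilobases and by the counted reads of the library) for each gene and library. Per the submitters' processing notes, FastQC, STAR, featureCounts and edgeR were used with the mm10 mouse genome; versions, settings, gene annotation and strand handling are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart. Genes with near-identical copies are uncertain too. Gapdh, which has many pseudogene copies, stood at 3.42 ± 1.37 RPKM in controls, and 6 haemoglobin genes were listed at 0 in every library.

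The table has 24062 rows, of which 24035 carry a gene symbol and 4567 of those are 0 in all libraries. In the other 27 rows a calendar date stands where a symbol should be, as spreadsheet programs write for some gene names. These held 0.233% to 0.269% of the counted reads. They were left out of the tests of named genes, since the table does not give their symbols and 4 of them share a date. Each gene's RPKM values in the 6 libraries are whole multiples of the worth of 1 read, so gene length and reads were recovered from the ratios between libraries. All 24062 rows (100%) came out as whole reads within a tolerance of 0.001 read, with a largest deviation of 9.31e-10 read and a median gene length of 2539 bp. The 4567 named rows at 0 count among them without a test. Each length is the smallest that fits, so length and reads can both be too small by a common factor. The counted reads behind the RPKM values were 40642612, 52544110 and 38936993 in control replicates 1 to 3, and 45252080, 40751014 and 58272424 in knockout replicates 1 to 3. At these depths 1 read in a gene of 1 kb is worth 0.0172 to 0.0257 RPKM, and named genes held 99.4% of the counted reads. Intervals and floors drawn from reads cover counting error only, since the reads carry no molecular identifiers.

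Genes with a mean of at least 0.5 RPKM over the 6 libraries were tested (13912 genes). Values were transformed to log2(RPKM + 0.5), and limma was fitted with a mean-variance trend in its empirical Bayes step, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A log2 change below is the knockout mean minus the control mean on this scale, which understates the change of low genes, and a fold is the ratio of the mean RPKM of the groups. No covariate entered the fit. For Klf4 an exact permutation test was added, whose smallest two-sided p with 3 against 3 libraries is 0.1.

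There were 19 gene lists: markers of podocytes, parietal epithelium, mesangium, endothelium, proximal tubule, loop with distal tubule and collecting duct, leukocytes and red blood cells, and genes of the cell cycle, JAK-STAT3 signalling, kidney injury, matrix and fibrosis, inflammatory cytokines and chemokines, the interferon response, actin cytoskeleton and adhesion, the KLF family, immediate-early and dissociation stress, nuclear oxidative phosphorylation and the sex chromosomes. The sex-linked list served only as a check of the animals, and red blood cell markers had under 5 tested genes, so 17 lists were tested. The test was limma's camera, which compares a list with all other genes, with a preset correlation between genes of 0.01. The lists were tested again with a correlation estimated from the data and with limma's fry, which asks whether the genes of a list move, on balance, one way and makes no comparison with other genes. Both were adjusted over the 17 lists. Counts of list members are given over all genes tested and adjusted over the list alone.

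The genes named are Klf4, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, the 4 members of each list with the smallest p, and Nphs1, Wt1, Synpo, Cldn1, Pax8, Cd44, Stat3 and Mki67. Some genes that this rule names are not reported here. The groups, test, filter, pseudocount, lists, naming rule and alternatives were fixed before the data were examined, except where a sentence says otherwise. Coordinates are 1-based positions from the RefSeq annotation of GRCm38.p6, the assembly that mm10 is built on, matched by symbol, since the table gives none. Of the 24035 symbols, 22550 matched a RefSeq symbol and 23895 a symbol or synonym. Of the genes tested, 13196 (94.9%) had coordinates.

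The alternatives were pseudocounts of 1 and 0.1, no filter, a filter at 2 RPKM, upper quartile scaling, quantile normalization, no trend, robust empirical Bayes, a proximal tubule score as covariate, the replicate number as a block, each library left out in turn, and other thresholds. After the data were seen, limma's voom on the recovered reads was added. The steps were tested on simulated data for the knockout against control comparison, in which 200 of 13460 genes were changed with a dispersion of 0.04: 69% of the genes changed 2-fold and 100% of those changed 4-fold were called, none in the wrong direction, together with 25 unchanged genes. In that run 169 changed genes were called beside the 25 unchanged ones. The unchanged genes were a larger share of these calls than the adjusted p threshold allows for on average. The 69% and 100% hold for the simulated dispersion only, and some real genes spread more widely. For example, the collecting duct gene Scnn1g stood at 14.3 ± 6.96 RPKM in knockouts. It had a log2 change of 1.56 and did not pass. The simulation therefore does not give the share of real changes that the test would call. With nothing changed, 2 genes and 0 lists were called. Simulated genes were drawn independently, so the 0 lists do not test camera where genes of a list are correlated. In the real data the estimated correlations within lists were 0.156 to 0.957. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.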

Results

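Glomerular RNA was compared between 3 control libraries, from mice with floxed Klf4, and 3 libraries with podocyte-specific Klf4 knockout, on the FVB/N background. The comparison asks how the glomerular transcriptome changes when podocytes, the epithelial cells that wrap the glomerular capillaries, lose Klf4, a zinc-finger transcription factor. Counted reads ranged from 38936993 to 58272424 per library. Correlations of log2 values were 0.969 to 0.981 between libraries of the same group and 0.891 to 0.949 between groups. The first principal component, with 66.6% of the variance, separated the groups. Values below are mean RPKM ± SD (n = 3 libraries per group), and adjusted p-values are from limma unless another test is named.

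Klf4 itself (chromosome 4, 55527137 to 55532475) did not differ in whole glomeruli. It stood at 21.5, 44.3 and 49.8 RPKM in control replicates 1 to 3 and at 29.4, 40.3 and 41.4 RPKM in knockout replicates 1 to 3. The means were 38.5 ± 15.01 and 37.0 ± 6.62 RPKM, with a log2 change of 0.015 (SE 0.31, 95% interval −0.71 to 0.74, adjusted p = 0.979, exact permutation p = 1). By the labels the deletion is in podocytes, so other glomerular cells would keep the gene. For this reason, and because the sources used here do not say which exons were deleted, this gene-level value does not check the labels. Its sign turned under both other scalings and without control replicate 1 (log2 change −0.35) or knockout replicates 2 or 3.

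Across the transcriptome 1389 genes were higher and 484 lower in knockout glomeruli, which is 13.5% of the 13912 tested. Of these, 932 were at least 2-fold higher and 253 at least 2-fold lower. The groups did not overlap for 4886 genes (35.1%, where chance gives 10%). Higher genes made up 74.2% of the calls. Under quantile normalization this share was 51.6%, with 849 higher and 798 lower, and the median log2 change of all tested genes moved from 0.097 to −0.048. Without knockout replicate 2 the counts were 474 higher and 124 lower. They were 839 and 237 without control replicate 1, 912 and 244 without control replicate 2, 823 and 321 without control replicate 3, and 941 and 209 without knockout replicate 1.

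**Figure D1:**
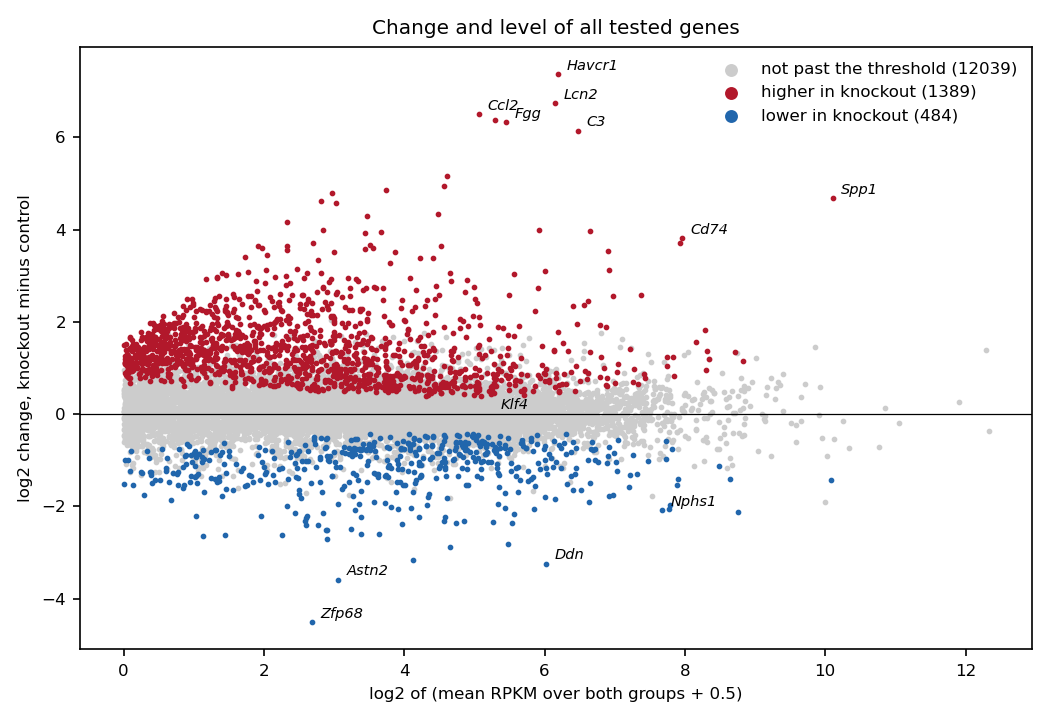
Log2 change of each of the 13912 tested genes (knockout minus control, on the log2(RPKM + 0.5) scale) against the log2 of its mean RPKM plus 0.5. Red points are the 1389 genes higher and blue points the 484 genes lower at an adjusted p under 0.05, grey points are the rest, Havcr1 lies highest at 7.36, Zfp68 lowest at −4.50 and Klf4 near 0.

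Podocyte genes fell. Of 33 podocyte markers tested, 18 were lower, 1 was higher and 14 did not pass, with a median log2 change of −1.35. The fall included Foxc2 and Wt1, transcription factors of podocyte development, from 47.7 ± 10.3 to 9.27 ± 2.93 RPKM (log2 change −2.32, SE 0.25, adjusted p = 2.90e-03) and from 110 ± 27.5 to 31.0 ± 11.5 RPKM (−1.84, SE 0.30, adjusted p = 9.98e-03). Synpo, which encodes the actin-associated protein synaptopodin, went from 349 ± 43.7 to 93.0 ± 33.0 RPKM (−1.96, SE 0.28, adjusted p = 6.98e-03), and Magi2, a scaffold of the slit diaphragm, from 21.8 ± 5.20 to 5.20 ± 1.95 RPKM (−2.01, SE 0.30, adjusted p = 8.45e-03). Nphs1 (chromosome 7, 30458207 to 30488623), which encodes nephrin of the slit diaphragm, dropped from 323 ± 86.8 to 84.0 ± 43.3 RPKM (−2.08, SE 0.45, adjusted p = 0.0254). Its call was lost with no filter and without control replicate 1 or 2, and its adjusted p ranged from 0.0188 to 0.0761 over the alternatives. Ptgds, a prostaglandin D2 synthase, went the other way, from 4.43 ± 1.81 to 20.6 ± 6.00 RPKM (2.13, SE 0.33, adjusted p = 9.01e-03). Adjusted over the list alone, 21 markers were lower and 1 higher. The list was lower by camera (adjusted p = 2.69e-16; adjusted p = 0.342 with an estimated correlation). The count of lower markers was 11 with no filter on low values, 7 without control replicate 1, 10 without control replicate 2, 11 without knockout replicate 1 and 10 without knockout replicate 2.

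Parietal epithelial markers, used here for the cells lining Bowman's capsule, rose. Of 20 tested, 12 were higher, 0 lower and 8 did not pass, with a median log2 change of 1.72. Cd44, a hyaluronan receptor that appears on activated parietal cells, rose from 0.509 ± 0.266 to 20.5 ± 10.8 RPKM (4.29, SE 0.36, adjusted p = 2.06e-03). Cldn1, a tight junction protein of the capsule, rose from 7.31 ± 1.99 to 49.7 ± 18.5 RPKM (2.65, SE 0.29, adjusted p = 3.30e-03). Pax8, a transcription factor of kidney epithelia, rose from 15.1 ± 1.69 to 38.3 ± 16.5 RPKM (1.24, SE 0.27, adjusted p = 0.0259), but lost the call with no filter and without each single control library in turn (adjusted p 0.0222 to 0.0702 over the alternatives). Cd74, the invariant chain of class II antigen presentation, which the leukocyte list also holds, rose 14.6-fold, and Cp, which encodes ceruloplasmin and is also an injury gene, rose 3.19-fold. Adjusted over the list alone, 18 were higher and 1 lower. The list was higher by camera (adjusted p = 9.15e-08; adjusted p = 0.342 with an estimated correlation). Of the 20 markers, 3 are shared with other lists. These values do not tell which cells the RNA came from, and leukocyte markers and kidney injury genes rose in the same libraries.

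Cell cycle genes rose almost throughout: 25 of 27 were higher, 0 lower, and 26 were higher when adjusted over the list alone. The median log2 change was 1.94. Without 1 library the count of higher genes was 19 to 22, lowest without knockout replicate 2. Mki67, which encodes the proliferation antigen Ki-67, rose from 0.469 ± 0.0797 to 7.48 ± 2.95 RPKM (2.97, SE 0.29, adjusted p = 2.34e-03). Ccna2, the cyclin of S phase and G2, rose 8.51-fold, Cdc20, an activator of the anaphase-promoting complex, rose 6.84-fold, and Mcm6, a subunit of the replicative helicase, rose 5.89-fold. Camera called the list higher (adjusted p = 7.86e-17; adjusted p = 0.314 with an estimated correlation). These genes do not tell which cell type was cycling, and markers of parietal epithelium and leukocytes rose in the same libraries.

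**Figure D2:**
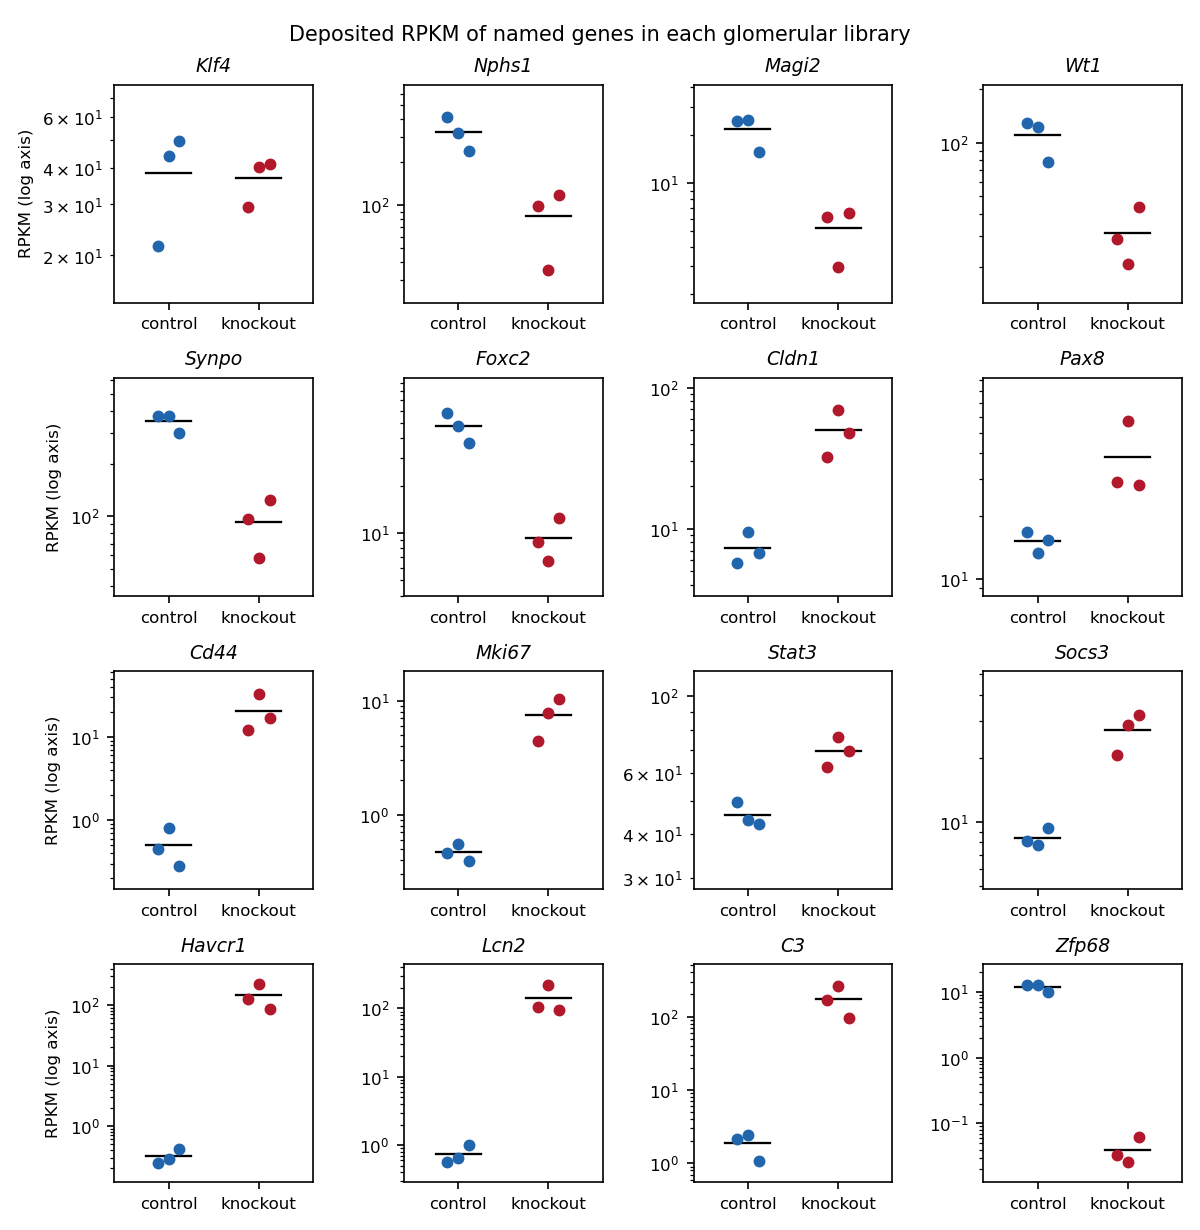
RPKM (log axis, a separate scale in each panel) of 16 named genes in the 3 control (blue) and 3 knockout (red) libraries. Each point is a library and each line a group mean; the groups overlap for Klf4 and are apart for the other 15 genes shown.

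Kidney injury genes were 5 of the 10 largest rises. Of 20 tested, 17 were higher and 0 lower, over all genes and over the list alone, with a median log2 change of 2.39. The count of higher genes was 12 with no filter and without control replicate 2 or 3 or knockout replicate 2. Havcr1 (chromosome 11, 46739822 to 46779578), which encodes KIM-1, a surface protein induced on injured tubule cells, rose 455-fold from 0.318 ± 0.0882 to 145 ± 71.8 RPKM (7.36, SE 0.32, adjusted p = 2.36e-04). Lcn2 (chromosome 2, 32384637 to 32387739), which encodes the injury marker NGAL, rose 189-fold to 140 ± 69.0 RPKM (6.73, SE 0.31, adjusted p = 2.57e-04). Fgg, a fibrinogen chain, rose 169-fold to 85.8 ± 43.6 RPKM, its neighbour Fga rose 52.5-fold, and complement C3 rose 93.4-fold to 176 ± 82.7 RPKM. The list was higher by camera (adjusted p = 5.07e-12; adjusted p = 0.314 with an estimated correlation).

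Few tubule markers passed in the same libraries. Of 19 proximal tubule markers, 1 was higher and 0 lower, both over all genes and over the list alone. The higher one was Slc5a12, a lactate transporter, which rose from 16.0 ± 3.43 to 63.7 ± 26.9 RPKM (1.88, SE 0.34, adjusted p = 0.0148) and lost the call without knockout replicate 2. Pck1, Slc5a2 and Gatm had log2 changes of −1.12, 0.97 and 0.85 and did not pass. The median log2 change of the list was −0.0073 and its mean 0.15, camera's direction was lower (adjusted p = 0.766) and fry's was higher (adjusted p = 0.801). Markers of the loop, distal tubule and collecting duct had a median log2 change of 1.20, with 1 of 15 higher over all genes and 3 over the list alone. That gene was Cldn16, a claudin of the thick ascending limb, which rose 4.60-fold (2.02, SE 0.38, adjusted p = 0.0171). Scnn1b, Scnn1g and Hsd11b2 of the collecting duct had log2 changes of 1.42, 1.56 and 1.51 and did not pass. Camera called the second list higher (adjusted p = 5.39e-03; adjusted p = 0.626 with an estimated correlation). That call was lost without control replicate 2 or knockout replicate 1, and the median fell to 0.74 without control replicate 2. Its count of higher genes was 8 with a proximal tubule score (the mean log2 value of the proximal tubule markers) as covariate, 7 without knockout replicate 3 and 0 without knockout replicate 1 or 2.

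Leukocyte markers rose with 15 of 16 higher, over all genes and over the list alone, and a median log2 change of 2.77. Class II antigen presentation genes were among the higher ones. H2-Ab1 rose from 11.1 ± 2.07 to 188 ± 70.6 RPKM (3.98, SE 0.26, adjusted p = 1.33e-03). H2-Aa rose from 17.5 ± 3.32 to 221 ± 103 RPKM, and Cd74 rose from 31.8 ± 9.37 to 465 ± 202 RPKM. Ccl5, a chemokine of T cells and macrophages, rose 24.9-fold. The complement C1q genes C1qa, C1qb and C1qc, made by macrophages, were also higher, with log2 changes of 3.51, 3.67 and 3.59 (chosen after their values were seen); C1qa lost the call without knockout replicate 2. Camera called the list higher (adjusted p = 2.14e-11; adjusted p = 0.314 with an estimated correlation). The T cell and B cell markers Cd3e, Cd79a and Ms4a1 stayed below the expression filter. With no filter, 12 of 19 members were higher and the median log2 change was 2.01. Without knockout replicate 2, 11 of 16 were higher. Cd3e had 15, 18 and 20 reads in control replicates 1 to 3 and 27, 41 and 55 in knockout replicates 1 to 3. The reads of Cd79a (27, 41 and 22 against 31, 27 and 32) and Ms4a1 (12, 34 and 2 against 22, 16 and 8) overlapped between the groups.

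Inflammatory cytokine and chemokine genes rose in 11 of 17 cases, with 0 lower, and 13 were higher over the list alone. Their median log2 change was 1.29 (1.97 with a pseudocount of 0.1). The count of higher genes was 8 without knockout replicate 2 and 9 without control replicate 1 or 2. Ccl2, the monocyte chemoattractant, rose from 0.158 ± 0.116 to 65.7 ± 35.6 RPKM (6.51, SE 0.40, adjusted p = 9.70e-04). Cxcl10, an interferon-induced chemokine, rose 11.7-fold, and Icam1, an adhesion molecule for leukocytes, rose 3.96-fold. Of 19 interferon-stimulated genes 10 were higher and 0 lower, 14 over the list alone, with a median log2 change of 0.97. Without control replicate 1 or 3 the count of higher genes was 7. Gbp3 and Irgm1, interferon-induced GTPases, rose 5.25-fold and 2.74-fold, Oasl2 rose 2.74-fold, and the transcription factor Irf7 rose 2.43-fold. Camera called both lists higher (adjusted p = 1.31e-07 and 2.38e-06; adjusted p = 0.314 and 0.376 with an estimated correlation). Both rises came in the libraries in which leukocyte markers were higher.

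Among genes of JAK-STAT3 signalling, 7 of 22 were higher and 1 lower, with 10 higher and 2 lower over the list alone and a median log2 change of 0.46. Stat3 rose from 45.5 ± 3.60 to 69.6 ± 6.97 RPKM (0.60, SE 0.13, adjusted p = 0.0249). That call was lost without control replicate 2 or 3 or knockout replicate 2, with an adjusted p of 0.0173 to 0.113 over the alternatives. Socs3, the feedback inhibitor that STAT3 induces, rose from 8.40 ± 0.843 to 27.2 ± 5.90 RPKM (1.62, SE 0.18, adjusted p = 3.37e-03). The STAT3 targets Bcl3, Myc and Timp1 rose 5.14-fold, 6.34-fold and 20.4-fold. Lif, an IL-6 family cytokine, and Osmr, the oncostatin M receptor, were higher (1.86 and 0.92), and Lifr, the receptor of LIF, was the lower gene (−0.57); these 3 were chosen after their values were seen. Osmr lost the call under both other scalings and without each single library, Lif without knockout replicate 2, and Lifr without each single library except knockout replicate 3, under quantile normalization, with no filter or a filter at 2 RPKM, with no trend and with voom. Camera called the list higher (adjusted p = 5.39e-03; adjusted p = 0.468 with an estimated correlation). Without knockout replicate 2 the count of higher genes was 4, and without control replicate 1 the median was 0.30. Of the 22 genes, 5 are shared with the stress, cell cycle and matrix lists: Socs3, Timp1, Ccnd1, Junb and Fos. The rise came in the libraries in which leukocyte markers were higher.

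Immediate-early and dissociation stress genes, which respond to tissue digestion, had 4 of 20 higher and 0 lower, 6 over the list alone, and were not called by camera (median log2 change 0.23, adjusted p = 0.235), though they were called higher under quantile normalization and without knockout replicate 1. The higher genes were Socs3, Atf3 (1.73, SE 0.33, adjusted p = 0.0173), Ier3 (0.87, SE 0.18, adjusted p = 0.0214) and Egr2 (1.45, SE 0.31, adjusted p = 0.0242). The count was 2 without each single control library or knockout replicate 2, and 6 without knockout replicate 1, and the median ranged from 0.078 to 0.42 without 1 library; Atf3, Ier3 and Egr2 each lost the call in some of these fits.

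Matrix and fibrosis genes rose in 13 of 24 cases, with 0 lower, and the median log2 change was 1.01. Fibronectin (Fn1) rose from 1.45 ± 0.519 to 42.3 ± 20.5 RPKM (4.34, SE 0.41, adjusted p = 2.06e-03). The fibrillar collagen genes Col1a1 and Col3a1 rose 27.0-fold and 18.4-fold. Over the list alone 17 were higher and 1 lower. Camera called the list higher (adjusted p = 1.94e-06; adjusted p = 0.376 with an estimated correlation). Without knockout replicate 2 the count was 8. The rise came in the libraries in which leukocyte and parietal epithelial markers were higher.

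Mesangial markers, of the contractile cells between the capillaries, moved both ways: 2 of 17 were higher and 4 lower, 3 and 9 over the list alone. The higher genes were the smooth muscle genes Tagln (from 28.8 ± 9.86 to 167 ± 74.8 RPKM, 2.46, SE 0.40, adjusted p = 0.0102) and Acta2 (3.70-fold). Sfrp2, a secreted Wnt modulator, fell from 578 ± 122 to 219 ± 51.2 RPKM (−1.41, SE 0.26, adjusted p = 0.0166), and Ptn, which encodes pleiotrophin, had a log2 change of −1.03 (SE 0.23, adjusted p = 0.0281). The other lower genes were Art3 and Hopx (−1.02 and −0.66), named after their values were seen; both lost the call without control replicate 2 or 3 or knockout replicate 2, and Hopx also without knockout replicate 1 and under quantile normalization. The median log2 change was −0.54 and the mean −0.090, and camera called the list lower (adjusted p = 5.39e-03; adjusted p = 0.535 with an estimated correlation), a call lost under quantile normalization and without control replicate 2. Lower markers numbered 0 without knockout replicate 2 and 1 without control replicate 2 or 3 or with no filter. Acta2, Ptn and Sfrp2 each lost the call without knockout replicate 2, Acta2 also without control replicate 1 or 3 or knockout replicate 3, Ptn also without control replicate 2 or 3, and both with no filter.

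Endothelial markers did not pass singly: 0 of 21 were higher or lower, over all genes or over the list alone. Ehd3, a marker of glomerular endothelium, stood at 545 ± 110 RPKM in controls and 265 ± 112 in knockouts (−1.09, SE 0.32, adjusted p = 0.0641). Emcn, Icam2 and Vwf had log2 changes of −0.91, −0.61 and 0.66. The median was −0.37, and camera called the list lower (adjusted p = 1.38e-03; adjusted p = 0.535 with an estimated correlation), a call lost under quantile normalization. The median was −0.20 without control replicate 2, −0.22 without knockout replicate 2 and −0.56 without knockout replicate 3. In the last fit, and with the proximal tubule score as covariate, 3 of these markers were lower. Of 24 actin cytoskeleton and adhesion genes, 2 were higher and 1 lower, over all genes and over the list alone (median 0.16, and 0.097 without control replicate 1; camera adjusted p = 0.986). Actn1, an actin crosslinker, rose 2.71-fold (1.40, SE 0.26, adjusted p = 0.0158), though not without control replicate 1 or knockout replicate 2. The count of higher genes was 0 without knockout replicate 2, and 3 were lower without knockout replicate 3. Synpo was the lower gene with all libraries, and Itga3, an integrin of podocytes, had a log2 change of −0.64 and did not pass.

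In the KLF family 1 of 15 genes passed, over all genes and over the list alone. Klf5 rose from 0.133 ± 0.0797 to 1.99 ± 0.626 RPKM (1.95, SE 0.24, adjusted p = 4.28e-03). Klf6, Klf13 and Klf15 had log2 changes of 0.81, −0.61 and −0.85 and did not pass. The list had a median of −0.0069 and a mean of 0.065, camera's direction was lower (adjusted p = 0.377) and fry's higher (adjusted p = 0.599). Without control replicate 1 camera called it lower, with 2 members lower. Nuclear oxidative phosphorylation genes had 0 of 26 past the threshold over all genes or over the list alone, with a median of 0.39 (0.23 to 0.62 without 1 library; camera adjusted p = 0.0755). With the proximal tubule score as covariate 4 were higher. The members with the smallest p, Cox5a, Uqcrc2, Ndufa4 and Cox6c, had log2 changes of 0.82, 0.50, 0.58 and 0.61. Of the red blood cell markers only Alas2, the erythroid haem synthesis enzyme, was tested (−0.88, adjusted p = 0.127); over the list alone it was lower. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were expressed in all 6 libraries and none passed over all genes (−0.57, 0.22, −0.11 and −0.056), while 1 of the 4 was lower over the list alone. Xist, expressed from the inactive X, was at or below 0.0343 RPKM in every library.

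Outside the lists, the 10 largest rises included epithelial and enzyme genes. Sprr1a, a cornified envelope precursor (chromosome 3, 92483954 to 92485881), rose 280-fold to 76.8 ± 52.6 RPKM (6.36, SE 0.53, adjusted p = 2.06e-03). Aoc1, which encodes diamine oxidase, rose 57.0-fold to 47.1 ± 22.8 RPKM, and Ubd, a ubiquitin-like protein induced by cytokines, rose 88.7-fold. Crct1, another cornified envelope gene, had 0 reads in each control and 220, 556 and 756 reads in knockout replicates 1 to 3 (14.6 ± 6.82 RPKM); its log2 change of 4.79 depends on the pseudocount.

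The largest fall was that of Zfp68, a zinc-finger gene (chromosome 5, 138603652 to 138619743). It went from 11.8 ± 1.65 to 0.0401 ± 0.0190 RPKM, 294-fold lower (−4.50, SE 0.17, adjusted p = 1.49e-04). Its recovered reads were 2477, 3121 and 1820 in control replicates 1 to 3 and 7, 5 and 17 in knockout replicates 1 to 3. Its neighbour A430033K04Rik and 5 of 71 other tested genes within 2 Mb were also lower, a region examined after the values were seen. Those 5 are 7.04% of the 71, against 3.48% of all tested genes with coordinates. Astn2, an astrotactin gene (chromosome 4, 65380803 to 66404537), fell from 14.9 ± 5.15 to 0.745 ± 0.185 RPKM (−3.58, SE 0.27, adjusted p = 1.81e-03). Ddn, which encodes dendrin of the slit diaphragm, fell from 116 ± 54.9 to 13.0 ± 7.69 RPKM (−3.24, SE 0.56, adjusted p = 0.0122). Shisa3 fell 6.90-fold, the organic anion transporter Slc22a7 fell 11.1-fold, the glycosyltransferase Mgat5b fell 30.2-fold, the potassium channel subunit Kcng2 fell 17.1-fold, and Ube2ql1 fell 9.69-fold. BC021614 and Gm6300 had log2 changes of −2.89 and −2.70; Gm6300 lost the call with no filter and without each single library except knockout replicate 1.

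**Figure D3:**
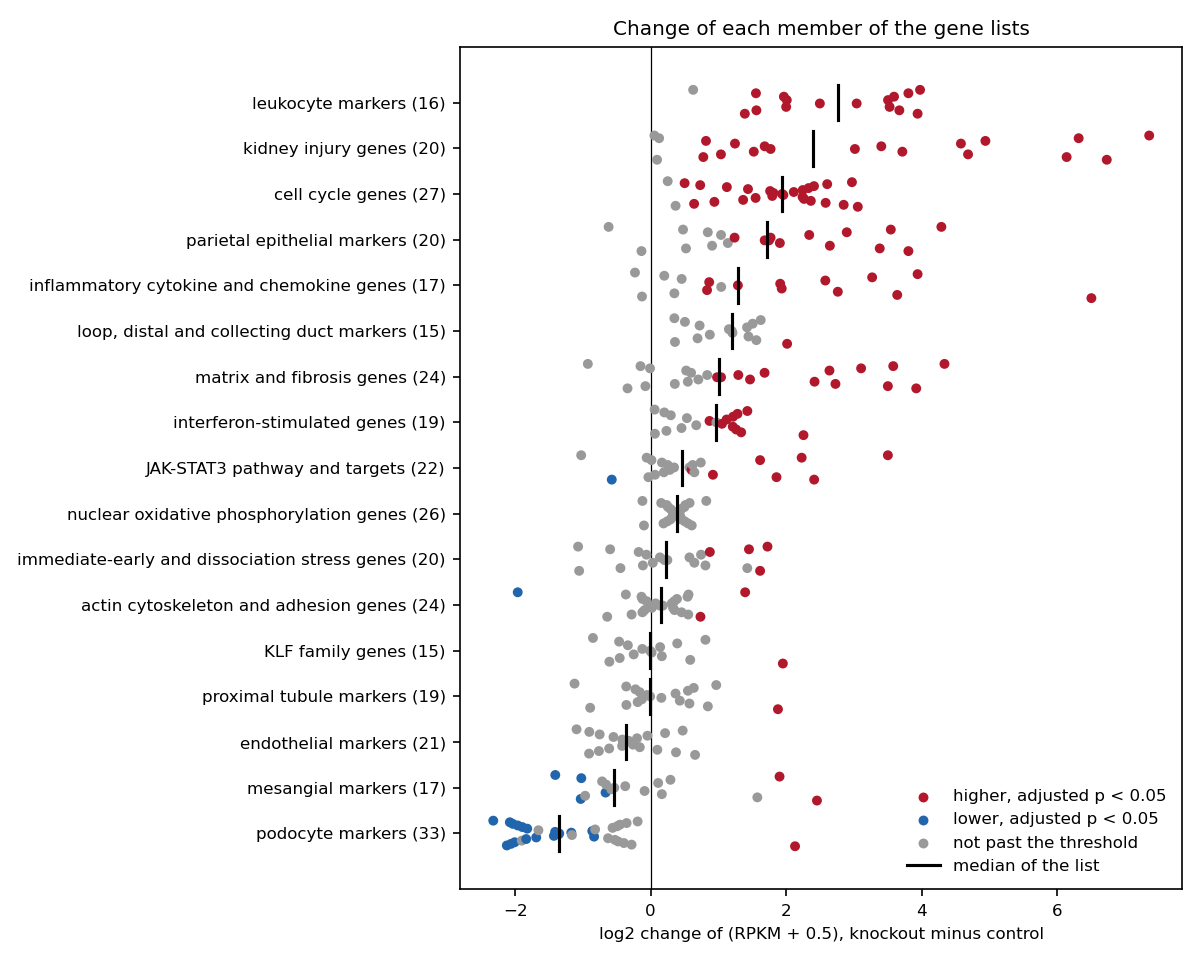
Log2 change (knockout minus control, RPKM + 0.5) of every tested member of the 17 lists, with the number of members tested in parentheses. Red points are higher and blue points lower at an adjusted p under 0.05, grey points did not pass, and bars mark medians, from 2.77 for leukocyte markers to −1.35 for podocyte markers.

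By camera with the preset correlation, 9 lists were higher and 3 lower. None of the 12 calls held with an estimated correlation, and fry called 8 lists higher and 1, the podocyte markers, lower (adjusted p = 0.0457). Other splits of the 6 libraries gave up to 10 lists higher and 7 lower by camera with the preset correlation. Those splits still hold part of the difference between the groups.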

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

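The fit on recovered reads was added after the data were seen; all other alternatives were planned. Of the 65 named genes past the threshold, 51 passed in every alternative that tested them and 14 lost the call in at least 1; among the 51, Mgat5b and Klf5 were not tested at the 2 RPKM filter. Counts of genes higher and lower stayed within 1.5 times the 1389 and 484 reported under pseudocounts of 1 and 0.1, no filter, upper quartile scaling, no trend, robust estimation, the proximal tubule score as covariate, and voom on recovered reads (1339 higher and 453 lower, of which 1276 and 427 were also called on RPKM). A filter at 2 RPKM gave 841 higher genes, all among the 1389, with fewer genes tested (11677). Quantile normalization gave 849 higher, 798 lower and 1 list lower; 845 and 462 of those genes were also called on the values as deposited. The cause was not tested. At an adjusted p under 0.1, a looser threshold, 2177 genes were higher and 855 lower. At the threshold of 0.05 with a change of at least 2-fold also required, 253 were lower. With fewer samples, leaving out 1 library at a time gave 474 to 1497 higher and 124 to 617 lower genes, both lowest without knockout replicate 2 and highest without knockout replicate 3. Lists by camera were 8 to 10 higher and 2 to 4 lower in those fits.

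Klf4 did not pass in any alternative, and its log2 change turned to −0.033 under upper quartile scaling and −0.0098 under quantile normalization; it ranged from −0.35 to 0.24 without 1 library. Uty ranged from −0.21 to 0.11, the latter without control replicate 2. The cause was not tested. With an estimated correlation camera called 0 lists higher and 0 lower, and fry called 1 lower. Nuclear oxidative phosphorylation genes were called higher under quantile normalization, a filter at 2 RPKM, the tubule covariate, voom, and without control replicate 3 or knockout replicate 3.

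The replicate numbers do not pair the libraries: deviations from the group means correlated at 0.18, −0.22 and −0.46 for replicates 1, 2 and 3, and 1 library correlated best with its own number. With the number as a block, 632 genes were higher and 179 lower, 9 podocyte markers were lower, and 8 named genes lost the call. Depth limits genes with few reads: 3 reads in a gene of 1 kb correspond to 0.0515 to 0.0770 RPKM.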

Other observations

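Tests of gene families, of the podocyte and injury patterns and of the Zfp68 region were chosen after the results were seen; the comparison with other splits of the libraries was planned. Families were formed from symbols that share the 2 to 6 letters before their first digit, or the prefix H2-, with at least 10 tested genes, and 340 one-sided Fisher's exact tests (170 families, both directions) were adjusted together; genes are not independent, so these p-values describe enrichment in these libraries only. Claudins, the proteins of tight junctions, were higher in 9 of 14 cases (adjusted p = 2.06e-04). Cldn4 rose from 3.25 ± 2.28 to 38.2 ± 21.5 RPKM, Cldn3 from 1.28 ± 0.663 to 13.2 ± 6.44, and Cldn6 was also higher (log2 change 1.80). Of the higher claudins, Cldn1 is also a parietal marker and Cldn16 a loop marker, and those lists had median changes of 1.72 and 1.20. Cldn5, a claudin of endothelium and podocytes, was the exception that fell, from 120 ± 61.3 to 38.6 ± 8.39 RPKM (−1.52, adjusted p = 0.0387). That call was lost without each single library except control replicate 3 (adjusted p 0.0175 to 0.153 over the 2 other scalings and the fits without 1 library). CC chemokines were higher in 9 of 14 cases (adjusted p = 2.06e-04), with Ccl20 at 0.0181 ± 0.0161 and 4.26 ± 2.56 RPKM in controls and knockouts, and Ccl7 at 0.00794 ± 0.0138 and 6.56 ± 3.65. Genes with an H2- symbol, most of them major histocompatibility genes, were higher in 11 of 23 cases (adjusted p = 4.65e-04), mostly class II and its loading factors such as H2-DMa (2.65) and H2-DMb2 (2.68). H2-Q1, a class I gene, fell from 192 ± 26.0 to 59.4 ± 21.0 RPKM (−1.74, adjusted p = 0.0103). Near-identical copies make reads of this family uncertain.

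Kinesin genes were higher in 9 of 27 cases (adjusted p = 0.0413), among them Kif11 and Kif23 (2.26 and 2.40), which act in mitosis or cytokinesis. Genes with a Col symbol, which are collagens except for Col4a3bp, were higher in 10 of 32 cases (adjusted p = 0.0413): Col5a3 rose from 0.343 ± 0.0832 to 11.7 ± 5.70 RPKM. Genes with a Cd symbol, a mixed set with many surface proteins, were higher in 17 of 53 cases (adjusted p = 7.35e-04). Histone genes went against the cell cycle genes, with 6 of 19 lower (adjusted p = 2.16e-03), such as Hist1h2be (from 2.45 ± 1.04 to 0.601 ± 0.231 RPKM) and Hist2h2be (from 5.00 ± 0.637 to 2.64 ± 0.399 RPKM). The histone count was 0 without control replicate 2 or knockout replicate 2 and 1 without control replicate 1 or knockout replicate 1. Both genes named lost their calls in these 4 fits. The reads of many histone genes depend on how the libraries selected RNA, which is not given in the sources used here. No called member of these 7 families changed sign under either other scaling or in the fits without 1 library. Without 1 library the counts were 4 to 9 for claudins (4 without knockout replicate 1 or 2), 5 to 9 for chemokines (5 without control replicate 1 or 2 or knockout replicate 2, and 5 under quantile normalization), 7 to 10 for H2- genes (7 without knockout replicate 2), 10 to 17 for Cd genes (10 without control replicate 1 or knockout replicate 2), 4 to 10 for Col genes (4 without knockout replicate 2, 6 without control replicate 3 and under quantile normalization) and 8 to 9 for kinesins.

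Other splits of the 6 libraries into 3 and 3 are 10 in all with the real one, too few for a share under 0.05. Each of the others mixes the groups unevenly, so it keeps part of the group difference and adds the rest to the spread. Their counts therefore do not show what the tests call when the groups do not differ. The real split gave 1389 genes higher and 484 lower, and the highest other split gave 0 and 0, so 1 of the 10 splits gave as many in either direction. For the lists, camera with the preset correlation called 9 higher and 3 lower in the real split, and the highest other splits gave 10 and 7. As many lists were higher in 3 of the 10 splits, and as many lower in 5.

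The podocyte markers were lower by a median of 1.35 on the log2 scale, with 18 of 33 past the threshold. Library scaling as the whole reason is argued against by a median log2 change of −1.30 under quantile normalization. A lower podocyte share as the only cause of all marker shifts would raise the markers of every other cell type alike. Leukocyte markers, however, exceeded endothelial markers by a median of 3.14 (95% bootstrap interval over genes 2.16 to 4.01). With estimated correlations of 0.509 and 0.542 within these lists, the interval does not measure the spread between libraries. Without 1 library the medians were 2.42 to 3.05 for leukocyte and −0.56 to −0.20 for endothelial markers. Whether the fall of the 18 markers came from fewer podocytes or from lower expression in each podocyte cannot be told apart, because no list of genes with podocytes as their single source was fixed and the log2 changes of the members ran from −2.32 to −0.19, apart from Ptgds, which rose. Loss of Klf4 in podocytes, Cre activity and scarring of glomeruli stay open as untested explanations.

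The kidney injury genes, with KIM-1 and NGAL among them, rose by a median of 2.39. More proximal tubule fragments of ordinary makeup in the knockout libraries would raise the proximal tubule markers about as much. The median change of the 19 listed markers was −0.0073, and it ranged from −0.34 to 0.34 without 1 library. For these markers as a set, that argues against such proximal fragments as the whole reason. It does not cover fragments of the loop, distal tubule or collecting duct, whose markers had a median change of 1.20. Slc5a12 was called higher, and proximal genes outside the list were not tested as a set. The upper 95% bootstrap bound of 0.55 for the median of the proximal markers is over genes. With an estimated correlation of 0.877 between them, it does not measure the spread between libraries. Injured tubule cells that had lost their proximal markers remain a candidate source, but no value here tests it. Loop, distal and collecting duct markers had a median change of 1.20 (lower 95% bootstrap bound over genes 0.69, estimated correlation 0.868). These genes mark other segments, so their rise does not show that proximal cells lost markers. The median fell to 0.74 without control replicate 2, and camera's call was lost without that library or knockout replicate 1. Fry did not call the list (adjusted p = 0.232). Injured tubule cells cannot be told apart from parietal or other glomerular epithelial cells that switched on the same genes. No value here assigns the transcripts to a cell type. Of the 20 injury genes, 2 (Vcam1 and Cp) are also parietal markers.

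Zfp68 and its neighbour A430033K04Rik (chromosome 5, 138622859 to 138648917), named after its values were seen, were nearly absent in knockout libraries: A430033K04Rik fell from 2.00 ± 0.267 to 0.194 ± 0.130 RPKM (−1.86, adjusted p = 3.25e-03). For Zfp68, less podocyte RNA is argued against, since the upper 95% bound of its change was −4.10. Foxc2, which fell furthest in the podocyte list, changed by −2.32. Zfp68 was picked as the largest fall, so its estimate lay below every listed marker by that choice. The bound takes no account of the choice. For A430033K04Rik, at −1.86, the same comparison does not argue against less podocyte RNA, though the scale understates changes of low genes. Ddn, a podocyte gene outside that list, changed by −3.24 (SE 0.56); as a ratio of mean RPKM it fell 8.98-fold and Zfp68 294-fold. A difference of the chromosome 5 segment between the groups, such as a strain variant or a transgene insertion, stays open. Within 2 Mb, 5 of 71 other tested genes were lower (7.04%, against 3.48% of tested genes with coordinates) and 5 were higher. Of the lower ones, Mir8116 lies within Ache and Ufsp1 next to it, so these calls may not be separate. Of 11719 windows elsewhere, which overlap one another, 9.70% held as many lower genes. This 9.70% passes the 5% bound set for arguing against a segment difference. However, a difference limited to Zfp68 and A430033K04Rik would leave their neighbours as they are. The segment therefore cannot be told apart from an effect of Klf4 loss. A loss confined to podocytes would bring Zfp68 this low only if other glomerular cells made almost none, which was not measured.

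Among the 27 rows with a date in place of a symbol, 19 were expressed enough to test, 0 were higher and 2 lower. The row for month 9, day 11 had 97.9 and 62.6 RPKM in controls and knockouts (−0.63, adjusted p = 0.0493), and the row for month 9, day 6 had 8.53 and 4.43 RPKM (−0.87, adjusted p = 0.0310). Il6, below the filter, had 0, 1 and 1 reads in control replicates 1 to 3 and 8, 21 and 34 in knockout replicates 1 to 3.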
